A study of Mus musculus with 4 samples.

How the data were processed

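Messenger RNA of lamina propria mononuclear cells was sequenced from stranded libraries in 4 mouse samples, per the labels' protocols, 2 after transfer of wild-type CD4 T cells and 2 after transfer of Hobit and Blimp-1 double-knockout CD4 T cells. Groups were taken from the treatment in the labels. Replicates were numbered in the order of their entries, and the numbers pair no samples. The series text speaks of 2 biological replicates per group but not of separate animals, so p-values measure the spread between these samples only.

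The values are log2 values, deposited by the authors as rlog, the regularized log2 of DESeq2, per the name of the deposited table and the submitters' processing notes. Those notes also name bcl2fastq 2.17.1.14, cutadapt 1.9.1, BWA 0.7.14-r1136, STAR 2.5.4a, Subread 1.5.2 with featureCounts, and the genome build GRCm38. The role and parameters of each tool, the annotation release and the version of DESeq2 are not given in the sources used here. Rlog pulls each gene towards its mean over the table, most where reads are few, so that folds of low genes are understated. The table also has 2 columns that match no labelled sample. They were not used here, but may have entered the authors' shrinkage. Counts and depth per sample were not analysed here, so no interval that rests on counts is given, and tests of counts were not made.

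The table held 48526 gene identifiers, of which 48058 were matched to a symbol and to a position in the GENCODE annotation of GRCm38. Values were 0 in all 4 samples for 23340. Genes with a mean rlog of at least 4 over the 4 samples were tested, 13528 in all. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for tables and figures. A linear model with group as its only term was fitted to each gene, followed by empirical Bayes moderation with a mean-variance trend (8.9 prior degrees of freedom beside 2 residual), and tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are DKO minus wild type on the rlog scale, with SE from the moderated fit.

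Before the data were examined, 33 gene lists of cell types, programmes and sample quality were fixed, with 549 genes, of which 495 were tested. Lists with at least 5 tested members (31 of 33) were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and with camera at an estimated correlation and fry, a self-contained rotation test of whether a list moves one way on balance. With an estimated correlation 0 of the 31 lists passed (2 had an unadjusted p under 0.05), and in fry 1 did (8 unadjusted), against 14 in camera at the preset correlation. The estimated correlation and its test rest on the 2 residual degrees of freedom, so a list can fail there without correlated genes. The neutrophil list failed (adjusted p = 0.251 in that test), though its estimate of -0.0438 was under the preset 0.01. It was the only called list of that kind. The estimates of the other called lists were above the preset value, from 0.0167 for replication-dependent histones to 0.751 for cell division. A failure there does not show that correlation between genes made the call, and does not exclude it either. The median, mean and test of each called list had the same sign. Some genes are in more than 1 list, such as Kit, Hdc, Lyve1, Ccl22 and Cxcl9. The text names Zfp683, Prdm1 and P2rx7, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose symbol is not a predicted or clone name, the up to 3 members of each list with the smallest p, and members a sentence counts by name. That rule was also fixed in advance, except that members were counted by name where at most 7 of a list moved one way, a number chosen after the values were seen. Some members that this rule takes are not reported here.

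Each test was repeated with no filter, with a mean rlog of at least 6, without the variance trend, with a robust variance estimate for genes only, with median centring, with quantile normalization, with sample weights and without each sample in turn. In fits without a sample the spread comes from the other group alone. A gene that passes or fails there may do so through that spread as well as through the sample left out. Calls were also counted at other thresholds, and lists tested on ranks. A correction for gene length, and random lists matched on the mean rlog of their genes, were added after the data were seen. The fit was tested on simulated data for the 13528 genes with the spread of the fitted prior. Of 67 genes changed by 0.25, 1.49% were recovered, of 67 changed by 0.5, 44.8%, and of 66 changed by 1, 98.5%, with 4 false calls among 100. The simulated genes varied independently, without the shrinkage of rlog, and 200 of them were changed, against 1998 calls in the data. These shares therefore check the code and need not hold for the data.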

Results

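RNA was sequenced from mononuclear cells of the lamina propria, the connective tissue layer under the gut epithelium, of mice that had received CD4 T cells. In 2 samples the transferred cells were wild type, and the labels describe pronounced colitis. In the other 2 samples the transferred cells lacked Hobit and Blimp-1, a pair of related transcriptional repressors of tissue-resident lymphocytes, and the labels describe mild colitis. These groups are called wild type and DKO (double knockout) below, although the genotype is that of the transferred cells and not of every cell in the sample. Each group had 2 biological replicates. The values are regularized log2 expression (rlog), which pulls differences towards 0, most in genes with few reads, and the depth of each sample is unknown. The median rlog over the 13528 tested genes lay between 8.33 and 8.35 in the 4 samples. The comparison asks how the lamina propria cells differ when the transferred CD4 cells lack the regulators of tissue residency.

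The transcripts of the deleted genes were measured in every sample, where they come from transferred and other cells alike. Zfp683, which encodes Hobit (ENSMUSG00000049410, GRCm38 chromosome 4, 134053838 to 134058996), had rlog values of 3.53 and 3.81 in the wild-type samples and 3.29 and 3.38 in the DKO samples. Its mean of 3.50 was under the minimum of 4 for testing, and with no minimum the difference of -0.34 (SE 0.122) had an adjusted p = 0.294 in limma. Prdm1, which encodes Blimp-1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501), stood at 11.53 and 11.43 in the wild-type samples and at 11.37 and 11.43 in the DKO samples (log2 fold change -0.077, SE 0.0817, adjusted p = 0.617). P2rx7, an ATP-gated ion channel named in the title of the study, was at 9.40 ± 0.108 (SD, n = 2) in wild type and 9.47 ± 0.175 in DKO (log2 fold change 0.078, SE 0.101, adjusted p = 0.693). The deleted part of each gene is not given in the sources used here, so these levels do not check the labels.

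Genes of connective tissue and blood vessels were higher in the DKO samples, and genes of neutrophils were lower. Postn, a matrix protein of fibroblasts, rose from 9.84 ± 0.0795 to 11.57 ± 0.173 (SD, n = 2 in each group), a fold of 3.32. Kdr, a receptor for vascular endothelial growth factor, rose from 7.38 ± 0.148 to 8.93 ± 0.0354, a fold of 2.93. Ngp, a neutrophil granule protein, fell by 2.26 on the log2 scale, from 11.90 ± 0.382 to 9.64 ± 0.339, and Ltf, which encodes lactoferrin, fell by 2.22. In limma with Benjamini-Hochberg adjustment, 1342 genes rose and 656 fell in DKO at an adjusted p under 0.05, and 67.2% of these calls were rises. Of these, 245 rose and 30 fell by more than 1 on the log2 scale. Over all tested genes, 55.3% had groups that did not overlap, against 33.3% on average over the possible splits into 2 and 2. Genes vary together, so a given split can exceed that average by chance, and the excess does not test the groups. The count of falls changed in fits without a single sample. There the lone sample of a group is assumed to vary like the other group. The change therefore cannot be laid to the values of the sample left out alone. With no filter on low values, 181 genes rose and 25 fell.

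Among genes with an established symbol, Hhip, an inhibitor of hedgehog signalling (chromosome 8, 79965851 to 80058006), had the largest rise, with a log2 fold change of 1.81 (SE 0.125, adjusted p = 1.26e-05). Timp3, an inhibitor of metalloproteinases bound to the matrix (chromosome 10, 86300372 to 86349506), rose from 9.64 ± 0.0178 to 11.41 ± 0.0073 (SD, n = 2), with an adjusted p = 1.58e-06. The growth factor Bmp4 rose by 1.76, the smooth muscle myosin Myh11 by 1.76 and the collagen Col12a1 by 1.61. Among vascular genes Podxl rose by 1.69, Adgrf5 by 1.67, Adgrl4 by 1.59 and the prostaglandin transporter Slco2a1 by 1.5, while Cpxm2 rose by 1.5. Among the 12 such genes with the largest fall, after Ngp and Ltf came Camp, the cathelicidin (-2.20, SE 0.316, adjusted p = 0.000682), and the T cell receptor segment Trbv14 (-1.72, SE 0.355, adjusted p = 0.00672, and a difference of -0.94 without wild-type replicate 2). The others were Mpo (myeloperoxidase, -1.64), Wfdc21 (-1.56), Tnfrsf26 (-1.56), Chil3 (-1.5), the collagenase Mmp8 (-1.48), Retnlg (-1.48), Ifitm6 (-1.45) and the calcium-binding protein S100a8 (-1.43). With a robust variance estimate Myh11, Camp, Trbv14, Mpo, Mmp8 and Retnlg did not pass (adjusted p = 0.202, 0.231, 0.347, 0.129, 0.214 and 0.126).

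**Figure D1:**
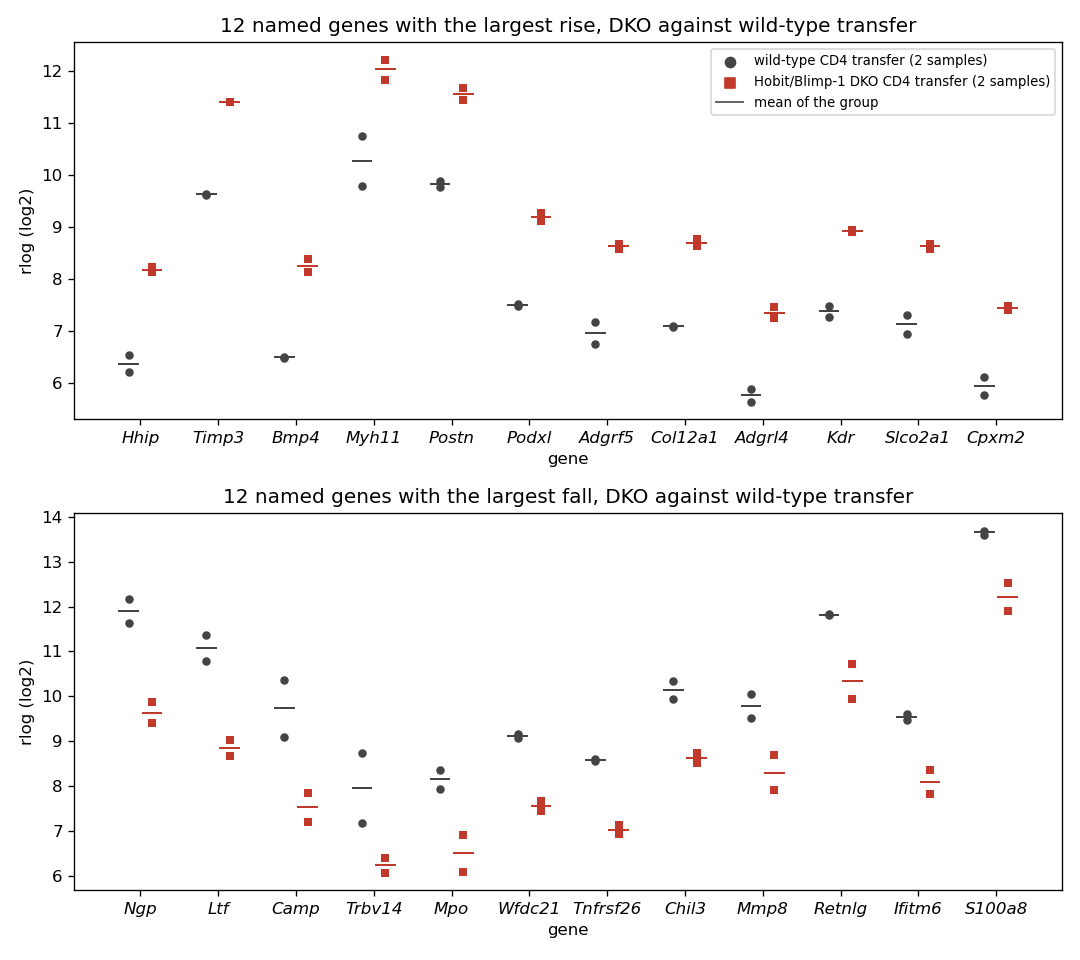
Regularized log2 expression (rlog, vertical axis) of the 12 named genes with the largest rise (upper panel) and the 12 with the largest fall (lower panel) in each of the 4 samples. Points are samples and lines are group means. In each gene both DKO samples lie on one side of both wild-type samples, as for Timp3, at 9.64 in wild type and 11.41 in DKO on average.

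The samples fell into their groups. Correlations of rlog over the 13528 genes were 0.9976 between the wild-type samples, 0.9966 between the DKO samples and 0.9882 to 0.9917 between groups. The mean squared difference was 0.0254 and 0.0342 within the groups and 0.0895 to 0.126 between them, and the mean over pairs of different groups was 3.69 times that over pairs of the same group. The first principal component held 77.0% of the variance and parted the groups, with wild type at -16.4 and -19.5 and DKO at 20.3 and 15.5. The second held 14.1% and parted the replicates within each group. No test was made of these distances.

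Neutrophil, monocyte and resident macrophage genes were lower as lists in camera. Of 22 neutrophil genes 21 fell, and 22 when adjusted over the list alone, with a median log2 fold change of -1.06. The falls were uneven, from -2.26 for Ngp to -0.26 for Il1r2. The receptor genes Cxcr2 (-0.72) and Csf3r (-0.50) also fell less than the median. Since members fell by different amounts, the median does not measure the share of neutrophils. The smallest p was that of Lcn2, which binds bacterial siderophores (-1.25, SE 0.0822, adjusted p = 1.03e-05). The list was lower in camera (adjusted p = 3.55e-22, and adjusted p = 0.251 with an estimated correlation) and was the 1 list past the threshold in fry (adjusted p = 0.00506). Of 17 monocyte genes 12 fell and 2 rose, and 14 fell and 2 rose when adjusted over the list alone (camera adjusted p = 7.42e-07, and adjusted p = 0.382 with an estimated correlation). Chil3 and Ly6c2 (-0.85, SE 0.0894) led the falls, and the members that rose were the matrix proteins Fn1 (0.73, SE 0.0841) and Vcan (0.69, SE 0.109). Of 17 resident macrophage genes 10 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000546, and adjusted p = 0.567 with an estimated correlation). The lipid receptor Trem2 fell by 0.97, and the member that rose was Lyve1 (1.07, SE 0.175), which lymphatic endothelium also expresses.

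Fibroblast, muscle and vessel genes rose. All 16 genes of fibroblasts and smooth muscle rose, also when adjusted over the list alone, with a median log2 fold change of 0.96 and a range of 0.51 to 1.76. After Postn, the collagen Col6a1 (1.15, SE 0.0914) and the proteoglycan Bgn (0.97, SE 0.0866) had the smallest p. The camera adjusted p was 6.57e-18, and adjusted p = 0.382 with an estimated correlation. All 13 endothelial genes rose as well, likewise when adjusted over the list alone, with a median of 1.2 (camera adjusted p = 3.03e-17, and adjusted p = 0.382 with an estimated correlation). Plvap, a protein of endothelial fenestrae, rose by 1.45 (SE 0.117), and the sialomucin Emcn by 1.44 (SE 0.116). Of 18 genes of matrix remodelling 8 rose and 3 fell, and 9 rose and 5 fell when adjusted over the list alone. Timp3, the aggrecanase Adamts4 (1.37, SE 0.148) and Timp2 (0.72, SE 0.0812) led the rises, and Plaur, Tgfbi and Adam8 fell by 0.55, 0.63 and 0.43. This list was higher in camera (adjusted p = 0.0317, and adjusted p = 0.625 with an estimated correlation). It did not pass in camera on ranks (adjusted p = 0.288) or without the variance trend (adjusted p = 0.0548). Nor did it pass without DKO replicate 2 (median 0.11 against 0.25). Adam8 did not pass without wild-type replicate 1 (-0.27, adjusted p = 0.22).

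**Figure D2:**
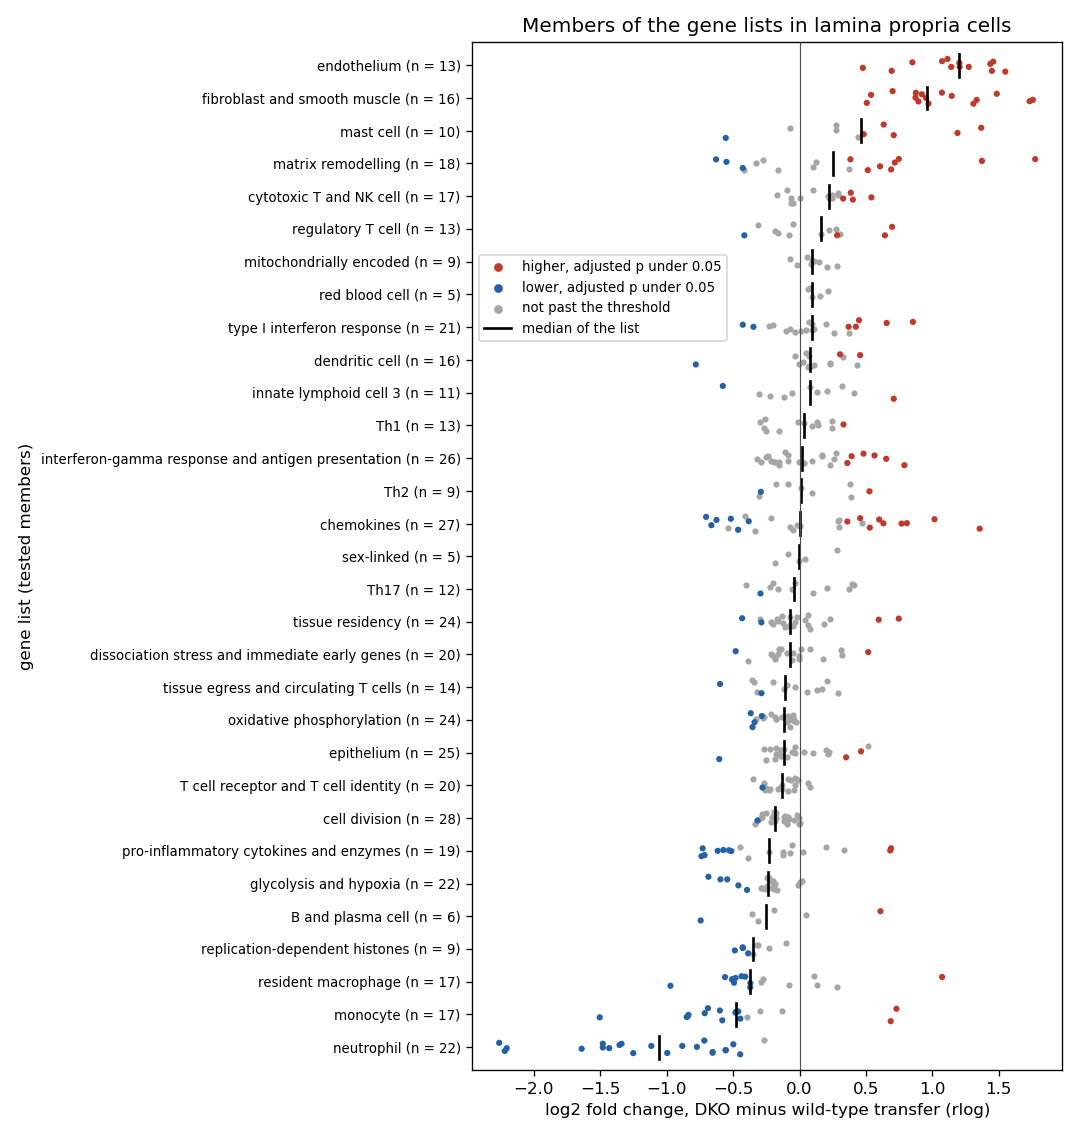
Log2 fold change, DKO minus wild type (horizontal axis, rlog scale), of every tested member of the 31 tested gene lists, ordered by the median of the list (black bar). Red and blue points rose and fell at an adjusted p under 0.05 in limma, and grey points did not pass. Endothelium (median 1.2) and fibroblasts and smooth muscle (0.96) lie at one end and neutrophils (-1.06) at the other.

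Mast cell genes were higher. Of 10 members 5 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000781, and adjusted p = 0.567 with an estimated correlation). The mast cell proteases Mcpt2 (1.37, SE 0.111) and Mcpt1 (1.19, SE 0.113) rose, with Kit, the receptor for stem cell factor (0.71, SE 0.0922), Mcpt4 (0.63, SE 0.165) and Gata2 (0.48, SE 0.117). The histidine decarboxylase gene Hdc, also in the neutrophil list, fell by 0.56. The median of 0.46 was 0.29 without DKO replicate 1, where Mcpt4 did not pass (0.35, adjusted p = 0.109), and Gata2 did not pass without wild-type replicate 1 or 2 or DKO replicate 2 (adjusted p = 0.0609, 0.0704 and 0.0539). Only 3 eosinophil genes and 3 genes of enteric neurons and glia were tested, too few for a test of the list. Ccr3 (-0.76, adjusted p = 0.0185) and Alox15 (-0.59, adjusted p = 0.0419) fell, and 2 fell when adjusted over the list alone. Tubb3 (0.46, adjusted p = 0.0211) and Ret (0.42, adjusted p = 0.0257) rose, and 3 rose when adjusted over the list alone. Without wild-type replicate 1, Ccr3 and Alox15 did not pass (-0.43 and -0.29, adjusted p = 0.121 and 0.343). Without wild-type replicate 2 Alox15 was at -0.89, and Tubb3 and Ret did not pass (adjusted p = 0.202 and 0.225), nor did Ret without DKO replicate 1 (adjusted p = 0.0742).

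Genes of inflammatory mediators were lower as a list, beside larger falls in the neutrophil list (median -1.06, 21 of 22 fell) and the monocyte list (median -0.48, 12 of 17 fell). Of 19 genes of inflammatory cytokines and enzymes 7 fell and 2 rose, and 9 fell and 2 rose when adjusted over the list alone. Osm, which encodes oncostatin M, fell by 0.73 (SE 0.0847, adjusted p = 0.000174), and so did Nos2, the inducible nitric oxide synthase (-0.74), Inhba (-0.71), Ptgs2, the inducible cyclooxygenase (-0.62), Il1a (-0.57), Il1b (-0.53) and Il12a (-0.51). Csf1, the growth factor of macrophages, rose by 0.69, and Il12b, a subunit of interleukin 12, rose by 0.68. The list was lower in camera (adjusted p = 0.0174, and adjusted p = 0.625 with an estimated correlation). It did not pass in camera with quantile normalization (adjusted p = 0.0615) or with the length correction (median -0.18, adjusted p = 0.0867). Nor did it pass without wild-type replicate 2 (median -0.16) or without DKO replicate 1 (median -0.20). The median of -0.23 was -0.46 without DKO replicate 2. Il1b did not pass without wild-type replicate 1 or 2 (adjusted p = 0.228 and 0.24), Ptgs2 without wild-type replicate 2 (adjusted p = 0.0831) and Il12a without wild-type replicate 2 or DKO replicate 1 (adjusted p = 0.0594 and 0.0668, with -0.32 in the latter). Nos2 was at -0.43 without DKO replicate 1, Il12b was at 0.45 without wild-type replicate 1, and Nos2 did not pass with a robust variance estimate (adjusted p = 0.156).

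Chemokine genes went both ways. Of 27 members 9 rose and 6 fell, and 12 rose and 7 fell when adjusted over the list alone, with no shift of the list in camera (adjusted p = 0.415), though the list was higher without wild-type replicate 2 (adjusted p = 0.0182). Ccl11, which attracts eosinophils, rose by 1.36 (SE 0.0852, adjusted p = 1.01e-05), and Cxcl12, a stromal chemokine, by 1.02 (SE 0.101). The falls were Cxcl3 (-0.66) and Cxcl2 (-0.63), ligands of the neutrophil receptor Cxcr2, and Ccl6 (-0.70), Ccl9 (-0.52), Ccl3 (-0.46) and Cxcl16 (-0.38). The Cxcr2 ligands Cxcl1 (-0.22, adjusted p = 0.368 in limma) and Cxcl5 (0.29, adjusted p = 0.317), looked up afterwards, did not pass. Cxcl2 and Ccl3 did not pass without wild-type replicate 2 (adjusted p = 0.0646 and 0.0542), nor Cxcl16 without wild-type replicate 1 or 2 or DKO replicate 1 (adjusted p = 0.0979, 0.0958 and 0.0606).

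Few T cell genes passed the test. Of 20 genes of T cell identity only Trat1, an adaptor of the T cell receptor, fell in limma (-0.28, SE 0.0812, adjusted p = 0.04). When adjusted over the list alone 0 passed, and 7 had an unadjusted p under 0.05. Bcl11b (-0.27, adjusted p = 0.0819) and Cd3d (-0.26, adjusted p = 0.0932) did not pass. The list was lower in camera with a median of -0.13 (adjusted p = 0.0174, and adjusted p = 0.676 with an estimated correlation), but this median lay inside the 95% range of random lists matched on level (-0.17 to -0.018). It did not pass without wild-type replicate 2 (median -0.08, adjusted p = 0.128), without DKO replicate 1 (median -0.073, adjusted p = 0.163) or with quantile normalization (median -0.048, adjusted p = 0.502). Trat1 did not pass without wild-type replicate 1 or 2 (adjusted p = 0.0727 and 0.375), while Bcl11b and Cd3d passed without DKO replicate 2 (adjusted p = 0.00549 and 0.0183). Of 17 cytotoxic and natural killer cell genes 4 rose, the receptors Klrk1 (0.33, SE 0.0776), Klri2 (0.54, SE 0.148) and Klre1 (0.40, SE 0.11) and the granzyme Gzma (0.39, SE 0.108), and 5 when adjusted over the list alone. In DKO replicate 2 Gzma stood at 13.01, against 12.45 to 12.69 in the other samples, and the genes of the CD8 coreceptor, chosen after their values were seen, were highest there too. Cd8b1 was at 8.09 in that sample and at 6.04, 6.10 and 6.04 elsewhere, and Cd8a at 9.64 and at 8.15, 8.92 and 8.23. This list of cytotoxic genes was higher in camera with a median of 0.22 (adjusted p = 0.0294, and adjusted p = 0.567 with an estimated correlation), but not without wild-type replicate 1 (median 0.13, adjusted p = 0.174) or DKO replicate 1 (median 0.073, adjusted p = 0.0735). Klrk1 did not pass without wild-type replicate 1 or 2 (adjusted p = 0.104 and 0.0853), Klri2 without wild-type replicate 2 (0.29, adjusted p = 0.293), Klre1 without wild-type replicate 1 or DKO replicate 1 (adjusted p = 0.253 and 0.0745), and Gzma without wild-type replicate 1 or 2 or DKO replicate 2 (adjusted p = 0.137, 0.124 and 0.0951, with 0.23 in the last).

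Genes of tissue residency and of tissue egress were not shifted as lists. Of 24 residency genes 2 rose and 2 fell, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.482). The integrin Itga1, which smooth muscle and vessels also express (0.75, SE 0.0892, adjusted p = 0.000206, beside medians of 0.96 and 1.2 in those lists), and the chemokine Xcl1 (0.60, SE 0.169, adjusted p = 0.0364) rose, and the gut homing receptor Ccr9 (-0.43, SE 0.107) and the phosphatase Dusp6 (-0.29, SE 0.0788) fell. Of 14 egress genes 2 fell, Lef1 (-0.60, SE 0.149) and S1pr1, the receptor by which lymphocytes leave tissues (-0.29, SE 0.077), and 3 when adjusted over the list alone (camera adjusted p = 0.242), with Klf2 at -0.35 (adjusted p = 0.0538). Xcl1 did not pass without wild-type replicate 1 or DKO replicate 1 (adjusted p = 0.073 and 0.13, with 0.27 in the latter and 0.93 without DKO replicate 2), nor Ccr9 without wild-type replicate 1 or DKO replicate 2 (adjusted p = 0.118 and 0.0512). Dusp6 (adjusted p = 0.123 and 0.252) and S1pr1 (adjusted p = 0.216 and 0.113) did not pass without wild-type replicate 1 or 2, and Lef1 was at -0.30 without DKO replicate 1. Klf2 passed without wild-type replicate 1 or DKO replicate 2 (adjusted p = 0.0199 and 0.00114), and was at -0.22 without wild-type replicate 2 (adjusted p = 0.455).

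The lists of helper and regulatory T cells and of innate lymphoid cells were not shifted in camera. Of 13 Th1 genes the interleukin 12 receptor chain Il12rb2 rose (0.33, SE 0.0827, adjusted p = 0.0205), and 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.97). Runx3 (-0.30, adjusted p = 0.0551) did not pass. Of 12 Th17 genes Batf fell (-0.30, SE 0.085, adjusted p = 0.0357), 0 passed when adjusted over the list alone (3 had an unadjusted p under 0.05 in limma), and Csf2 (0.40, adjusted p = 0.0901) and Il17f (0.37, adjusted p = 0.16) did not pass (camera adjusted p = 0.85). Of 9 Th2 genes Il5 rose (0.53, SE 0.144) and Ccr4 fell (-0.29, SE 0.085), likewise when adjusted over the list alone, and Il1rl1 was at 0.38 (adjusted p = 0.114, camera adjusted p = 0.97). Of 13 regulatory T cell genes Lrrc32 (0.70, SE 0.108), Nrp1 (0.64, SE 0.105) and Il2ra (0.28, SE 0.0796) rose and Il10 fell (-0.42, SE 0.126), and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.415, and 0.0353 without wild-type replicate 2). Endothelium also expresses Lrrc32 and Nrp1, and all 13 genes of its list rose (median 1.2), while Foxp3, looked up after the values were seen, was at 0.16 (SE 0.268, adjusted p = 0.77). Both DKO samples (7.02 and 7.43) lay between the wild-type samples (6.52 and 7.60), so the direction of Foxp3 depended on which wild-type sample is taken. Of 11 genes of group 3 innate lymphoid cells Kit rose and Arg1 fell (-0.58, SE 0.144), likewise when adjusted over the list alone, with Tnfsf11 at 0.32 (adjusted p = 0.0832, camera adjusted p = 0.719). Without wild-type replicate 1, Il12rb2, Batf, Il5, Ccr4 and Il2ra did not pass (adjusted p = 0.0707, 0.0553, 0.0776, 0.207 and 0.0994). Without wild-type replicate 2, these and Il10 and Arg1 did not (adjusted p = 0.186, 0.335, 0.0527, 0.186, 0.339, 0.453 and 0.206, with Il10 at -0.21 and Arg1 at -0.32). Without DKO replicate 1, Batf, Il5 and Il10 did not (adjusted p = 0.0831, 0.173 and 0.0734, with Il5 at 0.30), and without DKO replicate 2, Ccr4 did not (adjusted p = 0.0757). Newly past the threshold without DKO replicate 2 were Runx3, Csf2 (0.65), Il17f (0.63), Il1rl1 and Tnfsf11, and without wild-type replicate 2 Il1rl1 (0.65) and Tnfsf11. Single samples weighed heavily in these rises. Csf2 stood at 9.06 and 8.55 in DKO (8.36 and 8.45 in wild type), and Il17f at 6.71 and 6.21 (5.98 and 6.19). Tnfsf11 stood at 11.12 and 10.83 in DKO (10.54 and 10.78 in wild type), and Il1rl1 at 9.325 and 9.136 (8.583 and 9.112).

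Dendritic cell, B cell, epithelial and red blood cell lists showed no shift in camera. Of 16 dendritic cell genes Ccl22 (0.46, SE 0.0989) and Zbtb46 (0.30, SE 0.0907) rose and Siglech, a receptor of plasmacytoid dendritic cells, fell (-0.78, SE 0.182), and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.123). Only 6 of 17 B and plasma cell genes were high enough to be tested, so the list says little about these cells. Of the 6, Ebf1 rose (0.61, SE 0.112) and Sdc1 fell (-0.74, SE 0.118), likewise when adjusted over the list alone, and Igkc was at -0.31 (adjusted p = 0.16, camera adjusted p = 0.415). Of 25 epithelial genes the carbonic anhydrases Car1 (0.46, SE 0.0901) and Car2 (0.35, SE 0.0873) rose and Olfm4 fell (-0.60, SE 0.114), likewise when adjusted over the list alone (camera adjusted p = 0.498). Of 5 red blood cell genes 0 passed in limma, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.289), with Hbb-bt at 0.21, Hbb-bs at 0.15 and Alas2 at 0.093. Ccl22, Zbtb46 and Car2 did not pass without wild-type replicate 1 (adjusted p = 0.0668, 0.103 and 0.19), Zbtb46 and Car1 without wild-type replicate 2 (adjusted p = 0.295 and 0.0712), and Zbtb46 without DKO replicate 2 (adjusted p = 0.115), where Siglech was at -0.44. Igkc passed without DKO replicate 1 (-0.46), and Hbb-bt and Hbb-bs without DKO replicate 2 (0.29 and 0.34). Igkc stood at 6.68 and 6.39 in DKO replicates 1 and 2, against 6.74 and 6.96 in wild type. Hbb-bs stood at 13.97 and 13.59 in DKO, where replicate 2 lay under the wild-type mean of 13.63.

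Interferon response genes rose in part. Of 21 type I interferon genes 5 rose, Ifit3 (0.85, SE 0.1, adjusted p = 0.000182), Ifi44 (0.66), Mx2 (0.45), Usp18 (0.42) and Mx1 (0.37), and Oas3 (-0.43) and Isg15 (-0.35) fell, likewise when adjusted over the list alone (camera adjusted p = 0.167, and 0.0244 without DKO replicate 1). Of 26 genes of the interferon-gamma response and antigen presentation 6 rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.289). The immunity-related GTPases Irgm2 (0.79, SE 0.0814), Iigp1 (0.65, SE 0.107) and Igtp (0.39) rose, with the tryptophan-degrading enzyme Ido1 (0.56, SE 0.0976), the guanylate-binding protein Gbp6 (0.48) and the chemokine Cxcl9 (0.36). Without wild-type replicate 1, Oas3, Usp18, Mx1, Mx2, Isg15, Cxcl9 and Igtp did not pass (adjusted p = 0.0773, 0.0571, 0.0681, 0.065, 0.0692, 0.196 and 0.0668). Without wild-type replicate 2, Usp18, Mx1, Mx2, Isg15, Cxcl9 and Gbp6 did not (adjusted p = 0.0989, 0.152, 0.0722, 0.258, 0.0792 and 0.0625). Without DKO replicate 1, Usp18, Isg15, Cxcl9 and Gbp6 did not (adjusted p = 0.0619, 0.115, 0.0686 and 0.0864, with Gbp6 at 0.27), nor Mx2 without DKO replicate 2 (adjusted p = 0.0808).

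The lists of glycolysis and hypoxia, oxidative phosphorylation and cell division were lower in camera, though most members did not pass. Of 22 genes of glycolysis and hypoxia 5 fell, the lactate exporter Slc16a3 (-0.69, SE 0.099), the mitochondrial protein Bnip3 (-0.60, SE 0.105), the glucose transporter Slc2a1 (-0.54, SE 0.0885), Vegfa (-0.46) and Ero1l (-0.40), and 9 when adjusted over the list alone. The list had a median of -0.23, or -0.14 with quantile normalization (camera adjusted p = 5.29e-06, and adjusted p = 0.567 with an estimated correlation). Of 24 genes of oxidative phosphorylation 4 fell, Ndufa2 (-0.37), Cox5a (-0.35), Ndufb3 (-0.34) and Ndufa6 (-0.28), and 7 when adjusted over the list alone. This list had a median of -0.12, inside the 95% range of random lists matched on level (-0.15 to -0.015), or -0.18 without wild-type replicate 1 (camera adjusted p = 0.000663, and adjusted p = 0.665 with an estimated correlation), and did not pass with quantile normalization (median -0.061, adjusted p = 0.107). Of 28 genes of cell division Ccna2, a cyclin, fell (-0.32, SE 0.0931), 0 passed when adjusted over the list alone (7 had an unadjusted p under 0.05 in limma), and Birc5 (-0.31, adjusted p = 0.0507) and Ccnb1 (-0.29, adjusted p = 0.0737) did not pass. That list had a median of -0.19 (camera adjusted p = 0.000785, and adjusted p = 0.721 with an estimated correlation), and did not pass without wild-type replicate 1 (adjusted p = 0.0738) or DKO replicate 1 (median -0.055, adjusted p = 0.186). Vegfa (adjusted p = 0.104), Ndufa6 (0.0736) and Ccna2 (0.226) did not pass without wild-type replicate 1. Ero1l, Ndufa2, Cox5a, Ndufb3, Ndufa6 and Ccna2 did not without wild-type replicate 2 (adjusted p = 0.0688, 0.223, 0.305, 0.295, 0.357 and 0.0746), nor Ndufb3, Ndufa6 and Ccna2 without DKO replicate 1 (adjusted p = 0.0922, 0.076 and 0.167, with Ccna2 at -0.20), while Birc5 passed without DKO replicate 2 (adjusted p = 0.00106).

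Lists that bear on the quality of the preparations were read in the same way. Of 20 genes of dissociation stress and early response Fosb rose (0.52, SE 0.11) and Ier3 fell (-0.48, SE 0.107), likewise when adjusted over the list alone, and Nfkbia was at -0.39 (adjusted p = 0.0581, camera adjusted p = 0.486). Of 9 mitochondrially encoded genes 0 passed in limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.622), with mt-Cytb at 0.28, mt-Nd4 at 0.21 and mt-Nd2 at 0.15. The median of this list was 0.41 without DKO replicate 2, where the list passed, and -0.235 without DKO replicate 1. Its sign thus depended on the sample left out. Of 5 sex-linked genes 0 passed, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.97), with Kdm5d at 0.28, Eif2s3y at -0.18 and Ddx3y at -0.091. Of 9 replication-dependent histone genes 4 fell, Hist1h2bc (-0.49), Hist1h4i (-0.43), Hist1h1c (-0.43) and Hist1h4d (-0.39), and 7 when adjusted over the list alone. The histone list had a median of -0.35 (camera adjusted p = 0.000439, and adjusted p = 0.382 with an estimated correlation). Fosb did not pass without wild-type replicate 1 (adjusted p = 0.106) nor Ier3 and Hist1h2bc without wild-type replicate 2 (adjusted p = 0.0571 and 0.0517). Hist1h4i and Hist1h4d did not pass without either wild-type sample (adjusted p = 0.0858 and 0.132 without replicate 1, 0.0658 and 0.209 without replicate 2), and Hist1h4d did not pass without DKO replicate 2 (adjusted p = 0.0637). Without DKO replicate 2, Nfkbia, mt-Cytb, mt-Nd4, mt-Nd2 and Kdm5d passed (adjusted p = 0.00816, 0.0306, 0.0468, 0.00868 and 0.0273, with mt-Cytb at 0.62, mt-Nd4 at 0.46, mt-Nd2 at 0.55 and Kdm5d at 0.44), and without DKO replicate 1, Eif2s3y did (-0.37, adjusted p = 0.00907).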

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

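The length correction was chosen after seeing the data. Without any filter on low values, 181 genes were higher and 25 lower, against 1342 and 656, all of them among the main calls. That setting tests 25186 genes and also changes the moderated variance. The SE without the filter was 0.115 for P2rx7, against 0.101, and 0.067 for Prdm1, against 0.0817. At a similar ratio of change to SE, the unadjusted p in limma was 0.0491 without the filter (Zfp683, -0.34, SE 0.122). It was 0.0175 in the main fit (Cd3d, -0.256, SE 0.0915). The fit without the filter thus had fewer degrees of freedom, which raises p-values. How much of the drop in counts came from this and how much from the number of genes was not tested. With a mean rlog of at least 6, 878 were higher. At an adjusted p under 0.10, 1028 were lower, and at an unadjusted p under 0.05, 1635. With a log2 fold change beyond 1, 245 were higher and 30 lower, since small changes are left out. Without each sample in turn, genes higher ranged from 1008 to 1660 and genes lower from 324 to 1222, and gene lists higher from 4 to 7 and lower from 6 to 9. These fits have fewer samples, and the lone sample of a group is assumed to vary like the other group. With quantile normalization 8 lists were higher, against 5, and 6 lower, against 9, with the calls of oxidative phosphorylation, T cell identity and inflammatory cytokines lost. With camera at an estimated correlation, a test on 2 residual degrees of freedom, 0 lists were higher and 0 lower. With fry the counts were 0 and 1. The cause of the other differences was not tested. The ratio of mean squared differences between groups to those within them ranged from 3.40 to 3.79 under the 4 alternatives. No called gene changed sign in any fit, but most fits could not change one. The groups of all 1998 called genes did not overlap, so leaving out or weighting samples keeps the sign. The filters and variance settings leave the fold change as it was. Only median centring, quantile normalization and the length correction could have changed a sign. Of 1799 values of 151 named genes under the alternatives, 1492 kept their side of the threshold, 267 lost it and 40 gained it. Of 432 values of 31 lists, 381 kept it, 42 lost it and 9 gained it. Of 124 named genes that passed, 71 passed without each sample in turn, and 106 did not pass with no filter, 22 with quantile normalization, 16 without the variance trend, 14 with a robust variance estimate and 11 with the length correction. With the robust estimate Lef1, Klri2, Siglech, Ccr3, Alox15, Xcl1 and Il10 did not pass either (adjusted p = 0.17, 0.0513, 0.0523, 0.0849, 0.0674, 0.291 and 0.0999). With the length correction Batf, Il2ra, Zbtb46, Il10 and Isg15 did not (adjusted p = 0.0656, 0.0581, 0.134, 0.0718 and 0.121, with log2 fold changes of -0.23, 0.23, 0.22, -0.34 and -0.23 against -0.30, 0.28, 0.30, -0.42 and -0.35), nor did Alox15, at -0.58 against -0.59 (adjusted p = 0.0566), Ndufa2, Ndufb3, Hist1h4i and Hist1h4d, at -0.23, -0.22, -0.31 and -0.30 against -0.37, -0.34, -0.43 and -0.39 (adjusted p = 0.0697, 0.114, 0.0707 and 0.0994), Ndufa6, at -0.24 against -0.28 (adjusted p = 0.0511), nor did the list of inflammatory cytokines and enzymes (adjusted p = 0.0867). Matrix remodelling did not pass without the variance trend (adjusted p = 0.0548) or on ranks (adjusted p = 0.288). A robust variance estimate cannot be used in camera and was not run for lists. No paired analysis was possible because the replicate numbers come from the order of the entries and not from the labels. Depth is unknown, so what it limits cannot be read from these values.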

Other observations

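In this part the tests of cell shares, of expression level, of the ribosomal protein genes in camera, of the distances below all genes, of the T cell receptor segments and of other splits of the samples were chosen only after the result was seen, and so was the length correction itself, while the bounds for its tests were written before their results. Copies of ribosomal protein genes were left out after a first result, which changed no reading. The genes in this paragraph were chosen after their values were seen. The largest rise of all was that of Gm10036, a predicted gene on chromosome 18 (15832794 to 15833327), with rlog 5.40 and 5.58 in wild type and 7.97 and 8.28 in DKO (log2 fold change 2.64, SE 0.13, adjusted p = 3.69e-06). Dntt (log2 fold change -0.73, SE 0.122, adjusted p = 0.00178) and Ly6d (-1.11, SE 0.17, adjusted p = 0.000982), genes that lymphocyte progenitors express, fell. Dntt lay at 4.01 to 4.92, near the minimum of 4 for testing, and Rag1 was under that minimum (2.34 to 2.51). These values do not identify a cell type. Xist, transcribed from the inactive X chromosome, lay between 10.72 and 11.11 in all 4 samples, which also held transcripts of the Y chromosome, such as Ddx3y at 9.55 to 9.86 and Kdm5d at 6.50 to 7.04.

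Stromal and endothelial genes were higher in DKO while neutrophil genes were lower. A lower share of neutrophils alone would raise all other cell types alike, but the median of the endothelial list lay 1.34 above that of the T cell list (95% bootstrap interval over genes, which are not independent, 1.16 to 1.58). More tissue of every kind would bring epithelium too, but the fibroblast and smooth muscle list lay 1.08 above the epithelial list (0.917 to 1.38). With the trend on gene length removed, 50 of the 50 called members of the 3 lists still passed. A different yield of stroma in the preparation may account for part of the pattern, as may the difference in colitis between the groups, and the design holds these together, so both stay open and untested.

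Short and abundant genes were lower in DKO, with a median log2 fold change of -0.11 in the shortest eighth of genes and 0.055 in the longest, and of 0.077 in the eighth with the lowest mean rlog and -0.098 in that with the highest. With the length trend removed, medians were -0.117 for oxidative phosphorylation, -0.297 for histones and -0.184 for 74 ribosomal protein genes, a set chosen after the data were seen, against -0.117, -0.35 and -0.234 before (camera unadjusted p = 0.00888, 0.00589 and 1.43e-06, and unadjusted p = 0.427, 0.318 and 0.426 with an estimated correlation). Below the median of all genes, which moved from -0.022 to -0.053, the distance shrank from -0.0955 to -0.0637, from -0.329 to -0.244 and from -0.212 to -0.131. The fitted trend thus took away a part of each distance and not the whole. It was fitted to the joined length of all annotated exons, and any trend left among the shortest genes was not measured. The correction therefore cannot decide how far length is the cause. The level trend may account for the fall of oxidative phosphorylation, whose median lay inside the 95% range of 10000 random lists matched on level (-0.154 to -0.0154), but not for the whole of that of histones (-0.126 to 0.237) or ribosomal protein genes (-0.185 to -0.0796), whose medians lay below it, in random lists whose genes do not vary together. The authors' scaling may also account for a part, since with quantile normalization the oxidative phosphorylation list did not pass (adjusted p = 0.107) and the ribosomal median was -0.088, and no biological explanation was tested.

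T cell receptor beta variable segments varied between samples of a group, as with Trbv14 at 7.19 and 8.74 in wild type and Trbv29 at 6.33 and 5.10 in DKO. The median within-group SD of 17 segments was 0.345, against 0.101 for the median of 10000 random lists matched on level and 0.19 for the highest of them. A share of T cells that varies between samples would move all T cell genes, but the median SD of the 20 T cell identity genes was 0.101. Different clones expanded in each animal may account for the spread, a hypothesis found and tested on the same data. Reads shared between similar segments were not tested.

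The 4 samples can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 1998 genes, 1 of the 3 splits gave as many, and the highest other split gave 0 in limma, where the other splits gave 38 and 152 genes at an unadjusted p under 0.05. Each other split puts 1 sample of each real group on each side. The difference between the real groups then enters the residual spread and holds the calls down. The contrast of 1998 with 0 therefore says nothing about chance.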
